A study of Mus musculus with 13 samples.

How the data were processed

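RNA was measured in 13 libraries of nuclei from mouse heart ventricles, in a design of vector by sex. Per the labels' protocols, tissue nuclei were sorted for Pcm1, each library pooled 3 to 6 whole ventricles, RNA was isolated with TRIzol and column purification and depleted of ribosomal RNA, and strand-aware libraries were prepared. The authors deposited raw read counts per gene, with 1 column per library. The submitters' processing notes name STAR 2.5.3a, featureCounts 1.5.0 and the builds GRCm38 and mm10, without giving the role of each. No value was normalised before deposit: the counts are whole numbers and their totals differ between libraries.

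Per the file headers, each gene has a chromosome, a start, an end, a strand and a length. In all 55536 genes of the broader deposited table the length equalled the end minus the start plus 1, so the interval counted for a gene holds its introns as well as its exons. Nascent RNA can therefore contribute to the values, by an amount that was not measured here. The smaller deposited table held 15645 genes. These were exactly the genes with a mean count of at least 10 over the 13 libraries, and 0 of them had values that differed from the broader table. The broader table was analysed and the smaller one was an alternative. All 55536 identifiers were matched to GENCODE annotation of GRCm38, 22028 of them as protein-coding, and coordinates are those of the deposited tables. 24074 genes had 0 counts in every library. How reads were assigned where genes overlap is not given in the sources used here, and genes that lie wholly inside another gene on the same strand were mostly at 0, among them Cox4i1, Cpt1b, Myom1, Rpl13 and Ddit3, so a count of 0 for such a gene does not measure its expression. Etfb, also inside another gene, had 5 counts. Genes with near-identical copies, such as the class I histocompatibility genes and the interferon-inducible GTPases, are read with this limit, since reads shared between copies cannot be told apart in a count table.

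Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 4 groups, which left 16125 genes, and libraries were scaled with TMM factors. A quasi-likelihood model with 4 group means was fitted to all 13 libraries together, so that all groups shared 1 estimate of the spread, with a robust prior, and the quasi-likelihood test was applied to 6 contrasts with Benjamini-Hochberg adjustment over all tested genes. The contrasts were the vector effect in females, in males and averaged over the sexes, the difference of the vector effect between the sexes, and the sex difference under each vector. Log2 fold changes are PGR vector over control vector, or female over male. A standard error is the log2 fold change divided by the square root of its F statistic. CPM values are counts per M scaled with TMM. List means per library used log2 CPM with a prior count of 2. An adjusted p under 0.05 counts as passing.

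The groups, comparisons, test, alternatives, 29 gene lists and the rule for the genes named were fixed before the data were examined. The lists were written from general knowledge: cardiomyocyte identity, fetal and hypertrophy-associated genes, adult maturation, calcium handling, ion channels and gap junctions, fatty acid uptake and oxidation, glycolysis, citric acid cycle, nuclear-encoded respiratory chain, mitochondrially encoded transcripts, progesterone- and glucocorticoid-responsive genes, steroid receptors and cofactors, cell cycle, p53 response, interferon response, inflammation, immediate early genes, unfolded protein response, circadian clock, ribosomal protein transcripts, Y-linked and X-inactivation genes, and markers of fibroblasts, endothelium, smooth muscle and pericytes, macrophages, lymphocytes, adipocyte, epicardial and neural cells, atrial and conduction cells, and erythroid cells. Lists with at least 5 tested members were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and adjustment over the 28 lists tested, and again with an estimated correlation and with fry. The lymphocyte list was too short to test. Coverage was low in some others, with 14 of 28 members tested for inflammation and 6 of 22 for the adipocyte, epicardial and neural list. Means of a list per library were compared with exact two-sided permutation tests over all arrangements of the vector or sex labels. These number 700 for the averaged vector effect, 35 for 4 against 3 libraries, which gives a smallest p of 0.0286, and 20 for 3 against 3, which cannot give a p under 0.1.

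The rule named Pgr, Pcm1, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty in every comparison. It also took the 7 higher and 7 lower genes with the smallest p past the threshold and a mean log2 CPM of at least 1, or 5 and 5 for the difference between the sexes and for the PGR-vector sex comparison. Predicted or clone-named genes, small structural RNAs and mitochondrial genes were left out. Where no gene passed, it took the 5 with the smallest p. For each list described it took up to 4 members with the smallest p.

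Total counts per library ran from 31.8 to 86.3 M. The floor of 3 counts corresponds to 0.0348 CPM in the deepest library and 0.0945 CPM in the shallowest. Intervals at the 95% level and floors cover counting error only. Replicates are pools of separate ventricles per the labels, and no replicate pair held identical values: the chi-square per gene between replicates ran from 27.4 to 173. No sequencing batch, date or litter is given in the labels used here.

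The fit and camera were tested on simulated counts of the same 16125 genes. In each simulation 200 genes with a mean log2 CPM of at least 1 were changed, so recovery of lower genes was not tested. The interferon list was raised by 0.5 on the log2 scale besides. For the vector effect in females, 52% of genes changed by 0.5 on the log2 scale were recovered, with 98% at 1, 96% at 1.5 and 98% at 2, and 10 of 185 calls were false. For the vector effect in males the shares were 40%, 90%, 96% and 98%, with 12 false calls of 177. Calls on members of the raised interferon list counted as neither recovered nor false. This raised list had a camera p of 3.12e-12 in females and 7.67e-12 in males, and an unchanged list 0.756 and 0.842. Each gene was simulated independently, so this cannot show how often camera calls a list whose members vary together.

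Alternatives were other scalings, robust=FALSE, no filter or a stricter filter of CPM of at least 1 in 3 libraries, the authors' filtered table, the replicate number as a block, mitochondrial genes left out, only the compared groups in the fit, 1 surrogate variable (sva 3.50.0), limma-voom, DESeq2 1.42.0, a fold change of at least 1.5 besides, and each library left out in turn. A pair of alternatives was added after seeing the data: leaving out Con_F 4 and Con_M 3 together, and the mean of the endothelial and fibroblast lists as a covariate.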

Results

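The data were read counts per gene in nuclei from ventricles of C57BL/6J mice, a widely used inbred strain. Male and female pups received a single intraperitoneal injection of adeno-associated virus serotype 6 on postnatal day 1, and ventricles were collected on postnatal day 56. The virus carried either no insert (control vector, Con) or the human progesterone receptor (PGR vector, PGR), a steroid hormone receptor that acts as a transcription factor. Nuclei were sorted for Pcm1, a centriolar satellite protein that marks cardiomyocyte nuclei. The groups were control females (Con_F, 4 libraries), control males (Con_M, 3), PGR-vector females (PGR_F, 3, numbered 1, 2 and 4) and PGR-vector males (PGR_M, 3). Total counts were 37.6 to 58.9 M in Con_F, 33.3 to 86.3 M in Con_M, 31.8 to 55.5 M in PGR_F and 45.3 to 57.9 M in PGR_M.

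Genes that check the labels were read first. The human insert was not measured here. The mouse gene Pgr (ENSMUSG00000031870, GRCm38 chromosome 9, 8899833 to 8968611, plus strand) lay under the count filter, with 1 count in each Con_F library, 0, 0 and 1 in Con_M, 1, 5 and 6 in PGR_F and 8, 0 and 3 in PGR_M. Pcm1, the gene of the sorting marker, had 115 ± 13.5 CPM (SD, n = 4) in Con_F, 125 ± 3.93 (n = 3) in Con_M, 127 ± 11.6 (n = 3) in PGR_F and 123 ± 8.05 (n = 3) in PGR_M, and passed the test in none of the 6 comparisons. Xist, the RNA that coats the inactive X chromosome, had 1080 ± 48.1 CPM (n = 4) in Con_F and 989 ± 234 (n = 3) in PGR_F, against 0.474 ± 0.164 and 0.679 ± 0.330 (n = 3 each) in Con_M and PGR_M. Uty, on the Y chromosome, had 264 ± 16 CPM in Con_M and 251 ± 24.7 in PGR_M (n = 3 each), against 0.196 ± 0.0191 (n = 3) in PGR_F. In Con_F, Con_F 4 had 2.75 CPM of Uty and the other 3 libraries at most 0.208. Counts of Uty, Kdm5d, Ddx3y and Eif2s3y together stood at 1.01% of the male level in Con_F 4 (95% interval 0.859 to 1.18, 159 counts) and at 0.0112% to 0.112% in the other 6 female libraries.

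**Figure D1:**
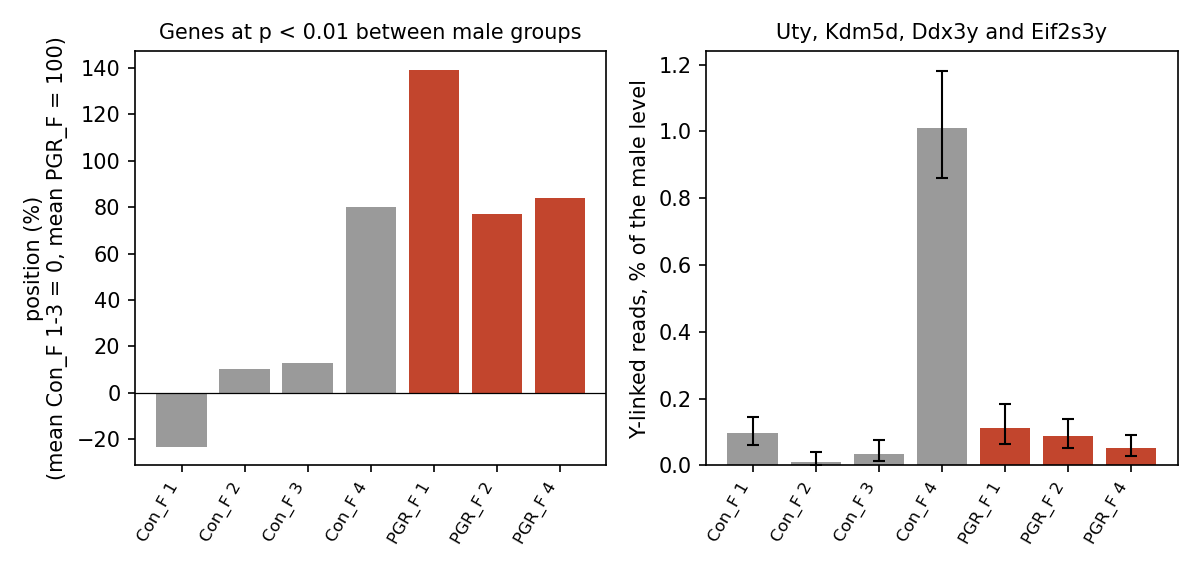
Left, position of each female library between the mean of Con_F 1 to 3 (0%) and the mean of PGR_F (100%) on the 424 genes with an unadjusted p under 0.01 between the male groups, where 0 genes passed after adjustment, 80.1% for Con_F 4. Right, reads of 4 Y-linked genes as a percentage of the male level, with 95% intervals of counting error, 1.01% for Con_F 4.

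The first comparison asked what the PGR vector changed in female ventricles. No single gene passed, and 5 gene lists passed camera with its preset correlation. Interferon-response genes, which act in antiviral defence and antigen presentation, were higher in PGR_F than in Con_F, with a median log2 fold change of 0.57 and 30 of 33 members above 0 (p = 0.0751 with an estimated correlation). Genes of fatty acid uptake and oxidation were also higher, with a median of 0.36 and 32 of 35 members above 0 (p = 0.174 with an estimated correlation). Genes of glycolysis (median -0.15, 24 of 30 below 0), of the nuclear-encoded respiratory chain (-0.09, 33 of 42) and of endothelium (-0.18, 26 of 27) were lower. The p with an estimated correlation was 0.113 for glycolysis, 0.248 for the respiratory chain and 0.405 for endothelium, and 0 of the 28 lists passed.

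The mean of the interferon list was 0.01, 0.28, 0.11 and 0.36 on the log2 scale in Con_F 1 to 4 and 1.27, 0.72 and 0.28 in PGR_F 1, 2 and 4, a difference of 0.57 (exact two-sided permutation p = 0.0857). Among interferon genes in females, 13 of 33 members were higher when adjusted over the list alone and 0 over all genes. Gbp2, an interferon-induced GTPase, had 0.539 ± 0.171 CPM (SD, n = 4) in Con_F and 1.49 ± 0.855 (n = 3) in PGR_F, a log2 fold change of 1.44 (SE 0.39, edgeR adjusted p = 0.302). The log2 fold change was 1.22 (SE 0.35) for B2m, the light chain of class I histocompatibility molecules. It was 1.30 (SE 0.38) for Tap1, a peptide transporter, and 0.70 (SE 0.22) for the transcription factor Irf1. Of the fatty acid genes, the dehydrogenase Acadl was at 0.37 (SE 0.12), the carnitine palmitoyltransferase Cpt2 at 0.37 (SE 0.14), Ehhadh at 0.54 (SE 0.21) and Hadha at 0.43 (SE 0.17), and 0 of 35 passed over the list alone. The glycolytic enzymes Pfkl, Gpi1 and Hk2 were at -0.46 (SE 0.12), -0.34 (SE 0.11) and -0.30 (SE 0.10), and the regulator Pfkfb3 at -0.34 (SE 0.16). The complex I subunits Ndufv1, Ndufb10 and Ndufb9 lay between -0.27 and -0.21. The endothelial genes Robo4, Sox17, Pecam1 and Erg lay between -0.78 and -0.29, and none of these members passed over its list alone. Camera's adjusted p was 4.24e-09 for interferon, 1.91e-08 for fatty acids, 0.000625 for glycolysis, 0.00401 for the respiratory chain and 0.00414 for endothelium.

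The female genes with the smallest p were Pmepa1 (log2 fold change -0.47, SE 0.07, edgeR adjusted p = 0.0659), which encodes a membrane protein known to restrain TGF-beta signalling, the copper-carrying ferroxidase Cp (0.74, SE 0.12), the coagulation inhibitor Tfpi (0.40, SE 0.07), Ccdc146 (0.50, SE 0.10) and Ehbp1l1 (-0.64, SE 0.12). EdgeR's quasi-likelihood test called 0 of 16125 genes, with 1765 at an unadjusted p under 0.05 against 806 expected by chance. Limma-voom called 0 and DESeq2 called 81. Without Con_F 4 edgeR called 20 genes and the endothelial call ended. Without PGR_F 1 the glycolysis, respiratory chain and endothelial calls ended, and without Con_F 1 or PGR_F 4 the respiratory chain call ended. The number of lists was 3 without PGR_F 1 and 10 without PGR_F 2. The difference of list means went from 0.57 to 0.31 for interferon and from -0.24 to -0.03 for endothelium without PGR_F 1, and from 0.42 to 0.20 for fatty acids without PGR_F 4.

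The same question was asked in male ventricles. The interferon list was again higher with the PGR vector, with a median log2 fold change of 1.20, 31 of 33 members above 0 and 25 past the threshold when adjusted over the list alone, against 0 over all genes. With an estimated correlation its p was 0.00623 (adjusted p = 0.174), and 0 lists passed in males. H2-D1, a class I histocompatibility heavy chain, had 2.25 ± 0.590 CPM in Con_M and 5.80 ± 0.323 in PGR_M (SD, n = 3 each). Irf1 had 1.25 ± 0.113 and 2.90 ± 0.239 CPM, Gbp2 0.265 ± 0.0950 and 1.19 ± 0.381, and the viral RNA sensor Ifih1 1.54 ± 0.245 and 3.28 ± 0.0474, in the same order. Genes of fatty acid oxidation (median 0.20, 32 of 35 above 0), atrial and conduction markers (0.23, 14 of 20), inflammation (0.30, 12 of 14), macrophage markers (0.33, 15 of 18) and endothelial markers (0.24, 26 of 27) were higher. Genes of the respiratory chain (-0.12, 38 of 42 below 0), the citric acid cycle (-0.09, 24 of 30) and glycolysis (-0.09, 19 of 30) were lower. With an estimated correlation the p was 0.0819 for the respiratory chain, 0.288 for fatty acids, 0.0922 for the citric acid cycle, 0.364 for endothelium, 0.0858 for atrial markers, 0.0841 for inflammation, 0.238 for macrophages and 0.266 for glycolysis.

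The log2 fold changes in males were 1.35 (SE 0.26) for H2-D1, 1.23 (SE 0.24) for Irf1, 2.10 (SE 0.46) for Gbp2 and 1.07 (SE 0.25) for Ifih1. Of the fatty acid genes, lipoprotein lipase Lpl was at 0.51 (SE 0.14), Ehhadh at 0.49 (SE 0.22), the fatty acid binding protein Fabp3 at 0.60 (SE 0.31) and Ucp3 at 0.74 (SE 0.42). Among atrial markers Sln, a regulator of the calcium pump, was at 2.00 (SE 0.57), Fgf12 at 1.79 (SE 0.64), the natriuretic peptide gene Nppa at 1.11 (SE 0.38) and Stard10 at 0.44 (SE 0.18). The leukocyte gene Ptprc was at 0.90 (SE 0.34) and Ctss at 0.84 (SE 0.36), while Fcer1g, from the same macrophage list, was at -0.40 (SE 0.15). The inflammation genes Birc3, Socs3, Icam1 and Tnfaip3 lay between 0.34 and 0.85, and the endothelial genes Fabp4, Kdr, Cyyr1 and Cdh5 between 0.37 and 0.44. Among energy genes the log2 fold changes were below 0: Pgk1 (-0.53, SE 0.12), Pgam1 (-0.41, SE 0.12) and Gpi1 (-0.40, SE 0.11) of glycolysis, which were the 3 that passed over the list alone. Around pyruvate dehydrogenase Pdhx (-0.43), Mpc2 (-0.31), Dld (-0.24) and Dlat (-0.22) were below 0, as were Cycs (-0.30), Ndufa8 (-0.26), Ndufb5 (-0.26) and Ndufb8 (-0.24) of the respiratory chain.

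Camera's adjusted p in males was 4.58e-28 for interferon, 6.81e-07 for the respiratory chain, 3.45e-05 for fatty acids, 6.62e-05 for the citric acid cycle, 0.00123 for endothelium, 0.00253 for atrial markers, 0.00708 for inflammation, 0.0115 for macrophages and 0.022 for glycolysis. Fry passed the interferon list alone (adjusted p = 0.0457), and the difference of its means, 1.02, had the smallest exact permutation p possible with 3 libraries against 3, 0.1. The genes with the smallest p were Pmepa1 (log2 fold change -0.51, SE 0.07, edgeR adjusted p = 0.0525), the G protein subunit Gng2 (1.26, SE 0.24), H2-D1, the amino acid transporter Slc38a1 (0.51, SE 0.10) and Irf1. EdgeR called 0 genes, with 1206 at an unadjusted p under 0.05 against 806 expected by chance, limma-voom called 0 and DESeq2 called 29. EdgeR called 1 gene without Con_F 4 and 3 without PGR_M 2. List calls ended without Con_M 2 (inflammation, endothelium, macrophages), Con_M 3 (glycolysis), PGR_M 1 (fatty acids, glycolysis), PGR_M 2 (glycolysis, endothelium, macrophages) or PGR_M 3 (endothelium). The difference of list means went from 0.32 to 0.20 for fatty acids without Con_M 1, and ranged from 0.09 to 0.51 for endothelium and from 0.13 to 0.55 for macrophages.

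**Figure D2:**
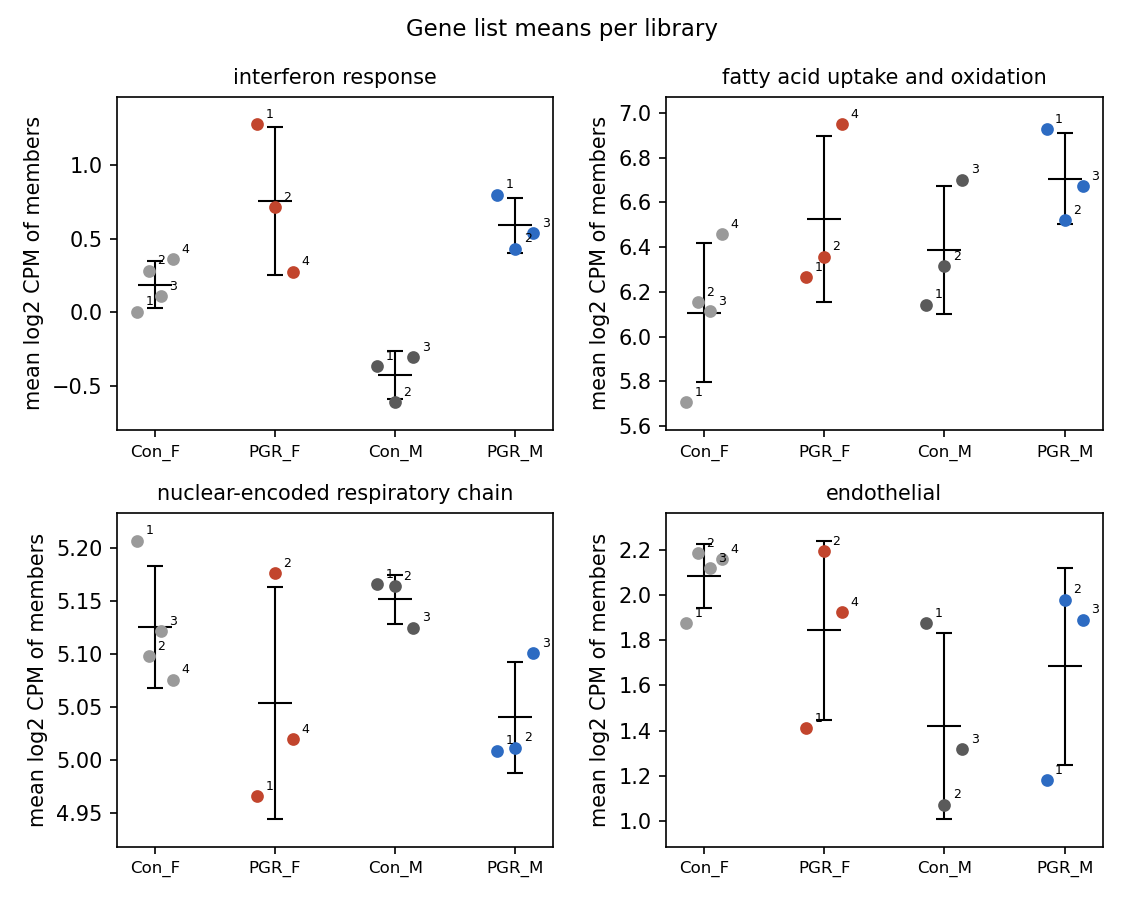
Mean log2 CPM of the members of 4 gene lists per library, with the group mean and SD as bars and the replicate number beside each point. The interferon means of PGR_M average 0.59 and those of Con_M -0.42.

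Averaged over the sexes, the PGR vector lowered Pmepa1 (ENSMUSG00000038400, GRCm38 chromosome 2, 173224458 to 173276533, minus strand), the only gene past the threshold. Its level was 46.5 ± 2.61 CPM (SD, n = 4) in Con_F and 33.5 ± 1.44 (n = 3) in PGR_F, 42.5 ± 0.525 in Con_M and 29.8 ± 0.427 in PGR_M (n = 3 each), a log2 fold change of -0.49 (SE 0.05, 0.711-fold, edgeR adjusted p = 0.000711). All 6 PGR-vector libraries lay under all 7 control libraries. Interferon genes were higher (median log2 fold change 0.88, 31 of 33 members above 0), as were genes of fatty acid oxidation (0.26, 33 of 35), while genes of the respiratory chain (-0.10, 35 of 42 below 0), glycolysis (-0.11, 23 of 30) and the citric acid cycle (-0.07, 22 of 30) were lower. With an estimated correlation 0 lists passed: the p was 0.0112 for interferon (adjusted p = 0.315), 0.155 for fatty acids, 0.0892 for the respiratory chain, 0.116 for glycolysis and 0.237 for the citric acid cycle.

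Over the interferon list alone 27 of 33 members were higher, and over all genes 0 were. Irf1 was at 0.96 (SE 0.16, edgeR adjusted p = 0.0607), Gbp2 at 1.77 (SE 0.30), H2-D1 at 0.94 (SE 0.17) and Tap1 at 1.59 (SE 0.29). In glycolysis 6 members were lower over the list alone, with Gpi1 at -0.37 (SE 0.08), Pfkl at -0.39 (SE 0.09), Pgk1 at -0.34 (SE 0.09) and Pgam1 at -0.28 (SE 0.08). Of the fatty acid genes Lpl was at 0.36 (SE 0.10), Ehhadh at 0.52 (SE 0.15), Cpt2 at 0.29 (SE 0.10) and Eci2 at 0.26 (SE 0.10), with 0 past the list-alone threshold. Ndufb10, Atp5g1 and Ndufv1 of the respiratory chain lay between -0.24 and -0.16, and Dlst, Mpc1, Mdh2 and Dlat of the citric acid cycle between -0.31 and -0.15. Camera's adjusted p was 1.48e-22 for interferon, 2.86e-09 for fatty acids, 1.04e-06 for the respiratory chain, 0.00055 for glycolysis and 0.0163 for the citric acid cycle. Fry passed interferon alone (adjusted p = 0.0213). The mean of the interferon list per library was higher by 0.79 on the log2 scale (exact two-sided permutation p = 0.00429 over 700 arrangements, adjusted p = 0.12 over 28 lists). The exact p was 0.0429 for the fatty acid mean (0.37 higher), 0.0314 for the respiratory chain mean (-0.09) and 0.0343 for the glycolysis mean (-0.10), each with an adjusted permutation p of 0.3.

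In the averaged comparison 2390 genes had an unadjusted p under 0.05 against 806 expected by chance, and 109 had an adjusted p under 0.1 in edgeR, 61 higher and 48 lower. The count of 1 gene became 338 without Con_F 4, 34 without PGR_F 4, 4 without PGR_M 2 and 2 without Con_M 3 or PGR_M 1, and DESeq2 called 334. The citric acid cycle call ended without Con_M 2, PGR_F 4, PGR_M 1 or PGR_M 2.

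**Figure D3:**
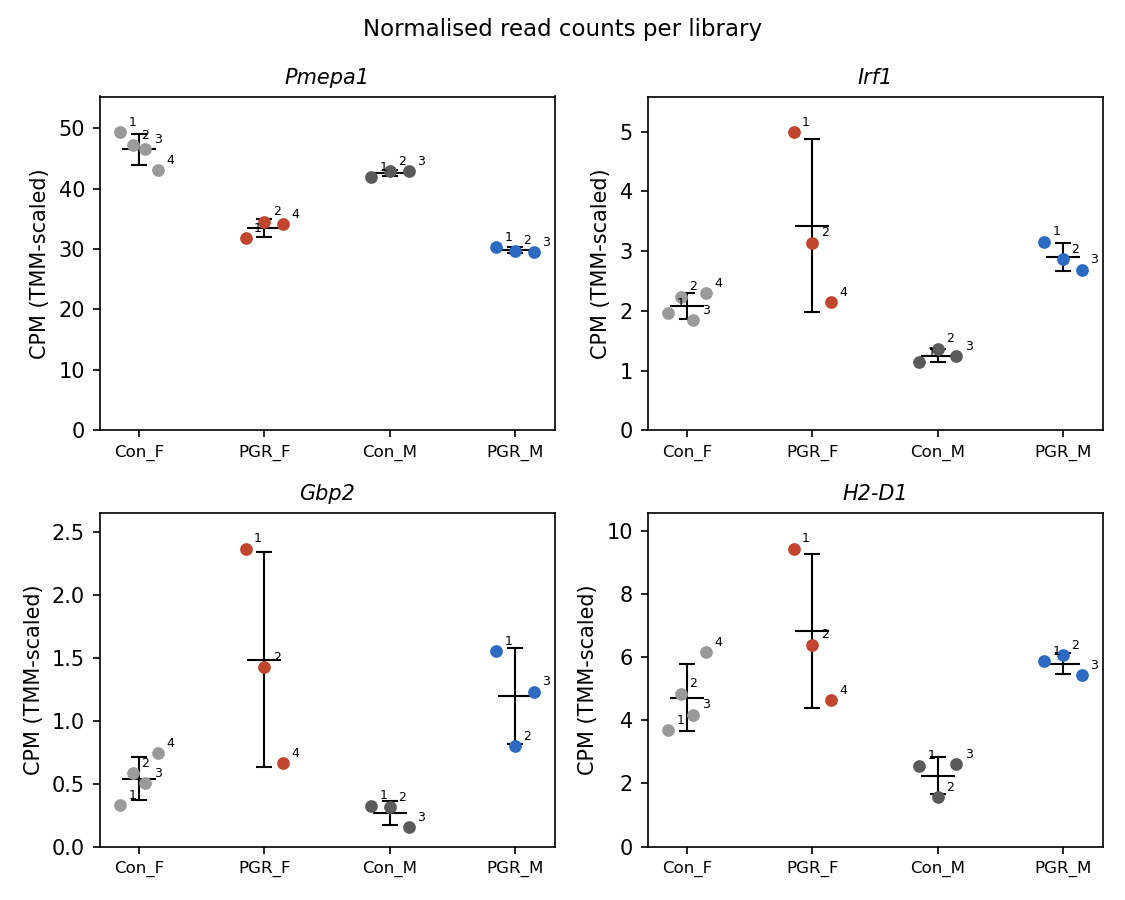
CPM per library of Pmepa1 and of the interferon-response genes Irf1, Gbp2 and H2-D1, with the group mean and SD as bars and the replicate number beside each point. Pmepa1 lies between 29.5 and 34.5 CPM in the PGR-vector libraries and between 41.9 and 49.3 CPM in the control libraries.

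**Figure D4:**
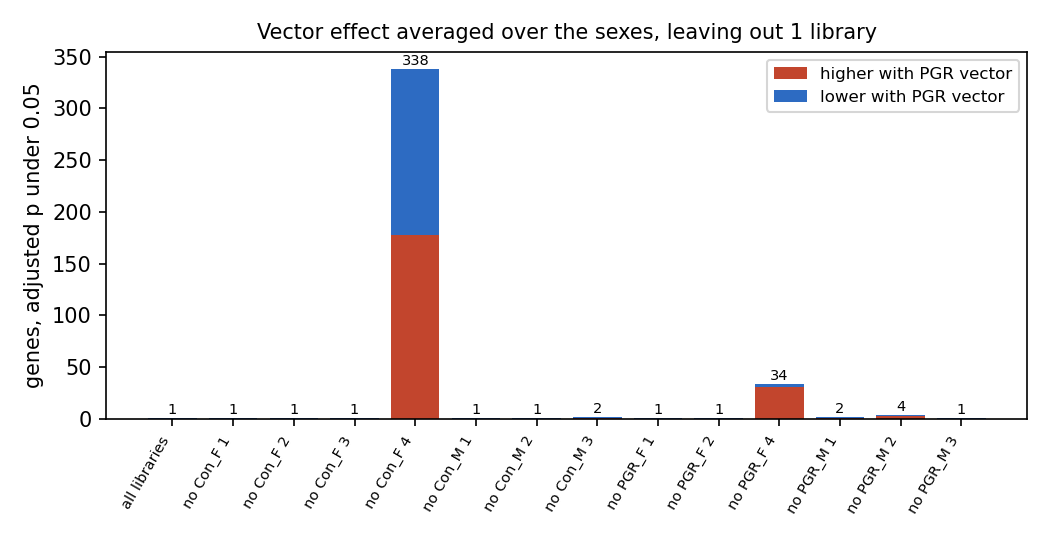
Number of genes past an adjusted p of 0.05 in edgeR for the vector effect averaged over the sexes, with all libraries and with each library left out, split by direction. The count is 1 with all libraries, 338 without Con_F 4 and 34 without PGR_F 4.

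Whether the vector effect differed between females and males was tested as an interaction. No single gene passed. As groups, endothelial markers (median difference, female minus male log2 fold change, -0.41, 27 of 27 below 0), interferon genes (-0.42, 27 of 33), fibroblast markers (-0.29, 22 of 28), atrial markers (-0.36, 14 of 20), smooth muscle and pericyte markers (-0.18, 12 of 15), inflammation (-0.21, 11 of 14) and progesterone- and glucocorticoid-responsive genes (-0.16, 24 of 35) were lower in females relative to males, and citric acid cycle genes (0.09, 24 of 30) were higher. The p with an estimated correlation was 0.147 for endothelium, 0.139 for interferon, 0.386 for fibroblasts, 0.169 for the citric acid cycle, 0.127 for atrial markers, 0.216 for smooth muscle, 0.132 for inflammation and 0.0851 for progesterone-responsive genes, and 0 lists passed with it or with fry. Markers of endothelium, fibroblasts and smooth muscle, cells other than those the Pcm1 gate selects, were thus lower together with the interferon list. The progesterone- and glucocorticoid-responsive list passed camera for the vector effect in neither sex, nor averaged. Only 35 of its 47 members were tested. Areg, Wnt4, Tnfsf11, Calcr and Cyp26a1 were among those under the count filter, so the result does not cover them. The mean of the tested members differed with the PGR vector by -0.018 log2 in females, 0.177 in males and 0.08 averaged (exact permutation p = 0.914, 0.2 and 0.301).

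The largest differences by p among interferon genes were Usp18 at -0.89 (SE 0.29), the immunoproteasome subunit Psmb8 at -1.92 (SE 0.77), H2-D1 at -0.83 (SE 0.34) and Rsad2 at -1.03 (SE 0.44). Sln was at -2.07 (SE 0.74), Fgf12 at -2.01 (SE 0.86), Nppa at -1.09 (SE 0.51) and Nr2f1 at -1.59 (SE 0.85). Of the progesterone- and glucocorticoid-responsive genes Ccnd1 was at -0.67 (SE 0.22), Cish at -0.99 (SE 0.33), Foxo3 at -0.29 (SE 0.18) and Ptch1 at 0.22 (SE 0.13). Robo4, Fabp4, Kdr and Esam of endothelium lay between -0.60 and -0.50, and Col1a2, Eln, Col1a1 and Postn of fibroblasts between -0.86 and -0.50. Mcam, Rgs5, Cspg4 and Smtn of smooth muscle and pericytes lay between -0.72 and -0.23, and Socs3, Vcam1, Il1r1 and Nfkb2 of inflammation between -1.16 and -0.27. Pdhx was at 0.53 (SE 0.17), Mpc2 at 0.38 (SE 0.13), Cs at 0.23 (SE 0.13) and Idh3a at 0.21 (SE 0.13). The single genes with the smallest p under the rule were Tfpi (0.52, SE 0.10), Ccdc146 (0.61, SE 0.14), Foxp2 (0.57, SE 0.16), Zc3h6 (0.69, SE 0.19) and Blcap (-0.33, SE 0.09), each with an edgeR adjusted p of 1.

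EdgeR called 0 genes in the interaction, with 525 at an unadjusted p under 0.05 against 806 expected by chance, while limma-voom called 0 and DESeq2 called 1. Camera's adjusted p was 2.44e-08 for endothelium, 3.33e-06 for interferon, 0.00311 for fibroblasts and for the citric acid cycle, 0.0144 for atrial markers, 0.0165 for smooth muscle, 0.0309 for inflammation and 0.0391 for progesterone-responsive genes. The number of lists fell to 3 without Con_M 2 or PGR_F 4 and to 4 without PGR_M 2, and the interferon call ended without PGR_F 4, the fibroblast call without Con_M 2, PGR_F 1 or PGR_M 2, and the citric acid cycle call without PGR_F 2. The atrial call held in 8, the smooth muscle and inflammation calls in 6 each and the progesterone-responsive call in 5 of the 13 fits that left out 1 library.

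Across the 16125 genes, the female and male log2 fold changes correlated with Pearson r = 0.307 and Spearman rho = 0.306, a correlation across genes, which are not independent replicates. The sexes share no library, so no shared control adds to this value. They had the same sign in 62.1% of genes. The correlation of the differences of group means, 0.338, had a two-sided permutation p of 0.02 over 700 arrangements of the vector labels within sex. At an unadjusted p under 0.05 in both sexes, 150 genes were higher and 135 lower in both, where independent lists would give 33.1 and 32.7, and 6 went opposite ways. Without PGR_F 1 the correlation was 0.194.

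**Figure D5:**
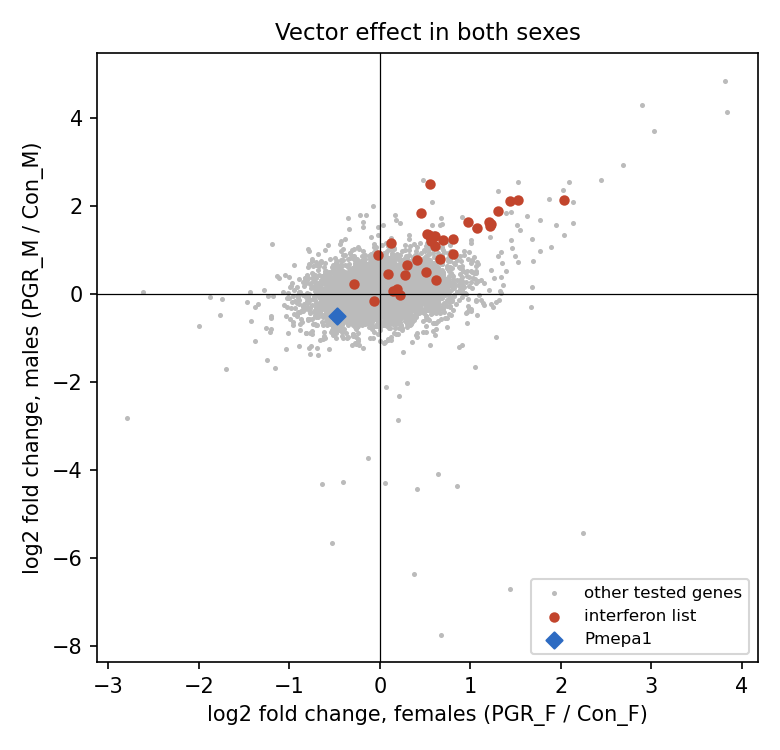
Log2 fold change of each tested gene with the PGR vector in females (horizontal) and males (vertical), 1 point per gene. The interferon list lies mostly above 0 on both axes, with medians of 0.57 in females and 1.20 in males, and Pmepa1 lies below 0 on both.

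The sex difference was examined in control-vector ventricles, where 37 genes passed, 16 higher in females and 21 higher in males. Of these 8 were on the X chromosome, 5 on the Y and 24 elsewhere. The X-linked genes Kdm6a (177 ± 20.3 CPM, n = 4, against 100 ± 4.06, n = 3; log2 fold change 0.82, SE 0.12), Kdm5c (0.68, SE 0.09), Eif2s3x (0.66, SE 0.10), Pbdc1 (0.62, SE 0.09) and Ddx3x (0.56, SE 0.09) were higher in females, several of them known to escape X inactivation, as was Rab10os (0.54, SE 0.09) on chromosome 12. Atp2b2, a plasma membrane calcium pump (-1.29, SE 0.19), the adenylyl cyclase Adcy8 (-0.92, SE 0.15) and Ano5, of the anoctamin family (-1.99, SE 0.32), were higher in males. Markers of endothelium (median 0.55, 26 of 27 above 0, 6 passing over the list alone), fibroblasts (0.67, 27 of 28) and macrophages (0.46, 16 of 18), and interferon genes (0.71, 31 of 33), were higher in Con_F than in Con_M in camera with its preset correlation. With an estimated correlation the p was 0.0843 for endothelium, 0.0971 for fibroblasts, 0.125 for macrophages and 0.0642 for interferon, and 0 of the 28 lists passed. Over the lists alone 1 fibroblast and 1 interferon member passed.

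On the Y chromosome Eif2s3y, Ddx3y, Kdm5d and Uty were lower in Con_F than in Con_M, with log2 fold changes between -8.92 and -8.53 and 0.0900, 0.134, 0.194 and 0.781 CPM in Con_F, values that rest on Con_F 4. The list of Y-linked and X-inactivation genes had 7 members higher and 4 lower over all genes, with a median of 0.49 and a mean of -1.34, which differ in sign (p = 0.0409, adjusted p = 0.453, with an estimated correlation). Among non-myocyte markers Pecam1 was at 0.72 (SE 0.19), Esam at 0.76 (SE 0.21), Mmrn2 at 0.77 (SE 0.26) and Fli1 at 0.55 (SE 0.18) for endothelium. The matrix genes Fbln1, Dpt, Col1a1 and Lum lay between 0.47 and 1.14. Notch3, Mcam, Pdgfrb and Itga8 of smooth muscle and pericytes lay between 0.59 and 0.67, and Ctss, Ptprc, Cd163 and Lyve1 of macrophages between 0.85 and 1.00. Wt1, Plin1 and L1cam of the adipocyte, epicardial and neural list lay between 0.52 and 1.76, and Cpne5, Sln, Nr2f1 and Fgf12 of the atrial list between 0.78 and 1.77. H2-D1 was at 1.05 (SE 0.25), Irf1 at 0.74 (SE 0.23), H2-K1 at 1.13 (SE 0.35) and Psmb8 at 1.80 (SE 0.62). The cell cycle list (median 0.34) was led by Cenpf, Cdk1, Mcm3 and Top2a, between 0.36 and 1.25, and the ribosomal protein list (0.14, 22 of 24 above 0) by Ftl1, Rps3, Rpl5 and Rplp0, between 0.14 and 0.35. The p with an estimated correlation was 0.216 for the cell cycle and 0.18 for ribosomal proteins. Lower in females were the fatty acid list (-0.28, 29 of 35), led by Eci2, Acadl, Acaa2 and Slc25a20 between -0.69 and -0.30 (p = 0.312 with an estimated correlation). So were the mitochondrially encoded transcripts (-0.43, 10 of 12), led by mt-Co3, mt-Nd2, mt-Nd1 and mt-Cytb between -0.82 and -0.48, and the citric acid cycle (-0.04, 21 of 30), led by Pdhx, Mpc2, Cs and Idh1 between -0.42 and -0.20. With an estimated correlation the p was 0.289 for mitochondrial transcripts and 0.351 for the citric acid cycle. Of the 13 lists passing camera, those of smooth muscle and pericytes (median 0.19), the adipocyte, epicardial and neural genes (0.47) and atrial genes (0.34) were also higher in females. The p with an estimated correlation was 0.235 for smooth muscle, 0.0671 for the adipocyte, epicardial and neural list and 0.0888 for atrial markers.

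For these 13 lists camera's adjusted p lay between 1.86e-12 for endothelium and 0.0446 for the citric acid cycle. Fry passed the sex-linked list alone (adjusted p = 0.00253). The gene count was 99 without Con_M 1, 92 without Con_F 4, 14 without Con_F 2 or Con_F 3, 15 without Con_M 2, 16 without Con_M 3, 22 without Con_F 1 or PGR_M 3, 23 without PGR_M 2 and 24 without PGR_F 2 or PGR_F 4. DESeq2 called 224 genes, no filter gave 131, only the compared groups in the fit 17, and the mean of the endothelial and fibroblast lists as a covariate 10. List calls ended without Con_F 2 (mitochondrial, cell cycle, adipocyte), Con_M 1 (mitochondrial, citric acid cycle), Con_M 2 (smooth muscle, citric acid cycle), Con_M 3 (fatty acids), Con_F 1 (smooth muscle), Con_F 3 (citric acid cycle) or Con_F 4 (citric acid cycle, sex-linked). Without Con_M 2 the difference of list means went from 0.74 to 0.45 for fibroblasts and from 0.47 to 0.27 for macrophages, without Con_F 1 from -0.28 to -0.15 for fatty acids, and without Con_F 4 from -0.41 to -0.64 for mitochondrial transcripts.

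In PGR-vector ventricles 23 genes differed between the sexes, 13 higher in females and 10 higher in males, with 10 on the X chromosome, 5 on the Y and 8 elsewhere. The X-linked genes Kdm6a (0.90, SE 0.12), Eif2s3x (0.77, SE 0.10), Ddx3x (0.69, SE 0.10) and the noncoding Jpx (0.59, SE 0.08) were higher in females. Atp2b2 was again higher in males, at 1.60 ± 0.101 CPM in PGR_F and 4.33 ± 0.806 in PGR_M (SD, n = 3 each; log2 fold change -1.43, SE 0.20). Eif2s3y, Ddx3y, Kdm5d and Uty lay between -10.34 and -9.60. Fibroblast markers (median 0.43, 25 of 28 above 0) and cell cycle genes (0.23, 23 of 28) were higher in females, and fatty acid genes (-0.14, 30 of 35 below 0) lower. With an estimated correlation the p was 0.279 for fibroblasts, 0.191 for the cell cycle and 0.446 for fatty acids, and 0 lists passed.

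Of the fibroblast genes in this comparison Comp was at 0.82 (SE 0.29), Lum at 0.98 (SE 0.34), Dpt at 0.74 (SE 0.27) and Thbs2 at 0.65 (SE 0.31). The cell cycle genes Cenpf and Cdk1 were at 0.56 (SE 0.12) and 1.47 (SE 0.40), Pcna at 0.51 (SE 0.18) and Ccnb2 at 0.55 (SE 0.24), with 2 members past the threshold over the list alone. Eci2, Ehhadh, Eci1 and Cd36 of the fatty acid list lay between -0.34 and -0.18. In the sex-linked list 9 members were higher and 4 lower over all genes, with a median of 0.59 and a mean of -1.72 (p = 0.0128, adjusted p = 0.36, with an estimated correlation). Camera's adjusted p was 7.88e-05 for the sex-linked list, 0.000114 for fibroblasts, 0.01 for fatty acids and 0.0136 for the cell cycle. Fry passed the sex-linked list alone (adjusted p = 0.0021). The gene count was 10 without PGR_F 1, 12 without PGR_F 2, PGR_M 2 or PGR_M 3 and 44 without Con_F 4, and DESeq2 called 80. List calls ended without PGR_F 1 (fatty acids, cell cycle), PGR_F 2 (fatty acids, fibroblasts), PGR_M 1 (fatty acids, fibroblasts) or PGR_M 3 (cell cycle), and 7 lists passed without PGR_M 2. The difference of list means ranged from 0.12 without PGR_M 1 to 0.68 without PGR_F 1 for fibroblasts and from -0.39 without PGR_F 4 to -0.05 without PGR_F 1 for fatty acids, and for the cell cycle went from 0.23 to 0.02 without PGR_F 1.

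The remaining lists passed camera in none of the 6 comparisons. For the averaged vector effect the median log2 fold change and camera's adjusted p were -0.04 and 0.504 for cardiomyocyte identity, -0.08 and 0.187 for fetal and hypertrophy-associated genes, -0.04 and 0.187 for adult maturation, -0.01 and 0.91 for calcium handling and 0.01 and 0.935 for ion channels. They were -0.02 and 0.504 for steroid receptors and cofactors, 0.06 and 0.193 for the p53 response, 0.08 and 0.637 for immediate early genes, 0.01 and 0.935 for the unfolded protein response, -0.14 and 0.43 for the circadian clock and -0.07 and 0.935 for erythroid genes. Reads of lymphocyte markers, which were too few to test as a list, amounted to 2.42 to 3.36 CPM in Con_F, 1.60 to 2.46 in Con_M, 3.05 to 5.65 in PGR_F and 1.92 to 3.70 in PGR_M.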

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

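The counts of other splits of the libraries, the tests of endothelial, fibroblast and macrophage admixture, of the Y-linked proportions, of admixture as the cause of the distance of Con_F 4, and of genes inside other genes were chosen only after the results were seen. The test of a wrong label for Con_F 4 was written before its result was seen.

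In Con_F, the only group of 4 libraries, single libraries stood far from the other 3. Con_F 4 had 0.476 CPM of Ddx3y (others 0 to 0.0346), 0.687 of Kdm5d (0 to 0.0866), 2.75 of Uty (0.0467 to 0.208), 16.5 of Pgk1 (21.8 to 22.1), 13.8 of Pgam1 (16.9 to 17.2) and 1.19 of Icam1 (0.797 to 0.817). Con_F 1 had 82.6 CPM of Ndufv1 (others 70.5 to 72.4), 5.28 of Kdr (7.40 to 7.75), 1.20 of Vcam1 (2.01 to 2.15), 35.8 of Idh1 (45.0 to 45.8) and 2.51 of Dpt (3.28 to 3.38), and Con_F 2 had 8.33 of Pdgfrb (7.12 to 7.20). These were 12 of 173 quantities, where chance gives 8.7, and 6 of them concerned Con_F 4.

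The vector effect differed between the sexes for 8 lists in camera with its preset correlation, and for none with an estimated correlation. The median differences, females minus males, were -0.413 for endothelium, -0.417 for interferon, -0.291 for fibroblasts, -0.356 for atrial genes, -0.179 for smooth muscle and pericytes, -0.205 for inflammation, -0.161 for progesterone- and glucocorticoid-responsive genes and 0.09 for the citric acid cycle.

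Mouse Pgr lay under the filter of the comparisons, and its few reads gave pooled rates that differed between the vectors. In females there were 4 of 181.5 M counts with the control vector and 12 of 134.7 M with the PGR vector, a ratio of 4.04 (95% interval of counting error 1.23 to 17.2, exact permutation p = 0.0286), but PGR_F 1 had 1 count, as each Con_F library did, and lay above them in that test only through its lower depth. In males there were 1 of 155.8 M and 11 of 153.8 M, a ratio of 11.1 (1.62 to 480, exact permutation p = 0.4), with 8 of the 11 counts in PGR_M 1 and 0 in PGR_M 2. The counts do not show whether these reads came from the mouse gene or from the human insert.

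The interferon list was higher with the PGR vector in both sexes in camera with its preset correlation, but in neither after adjustment with an estimated correlation (p = 0.0751 in females, adjusted p = 0.174 in males; exact permutation p = 0.0857 and 0.1). Averaged over the sexes, the endothelial and fibroblast list means differed by 0.01 and -0.019 log2 between the vectors. This argues against more of these nuclei for the averaged effect only. With the mean of these lists as a covariate the median was 0.84 (SD of the members 0.533), against 0.883 without it. A covariate so alike between the vectors could hardly move that median. In males both list means were higher with the PGR vector (0.262 and 0.148). The joint mean of these lists overlapped, at 1.319 to 2.265 log2 CPM in PGR_M and 1.184 to 2.049 in Con_M. The male interferon means did not overlap (0.59 ± 0.188 in PGR_M, -0.425 ± 0.163 in Con_M, SD, n = 3 each). With the covariate the male interferon call in camera held. These values argue against more such nuclei as the whole source in males, and a part stays open. The averaged vector effect on the interferon mean exceeded that on the macrophage mean by 0.608 log2 (exact permutation p = 0.00143 over 700 arrangements). This argues against more macrophages as the whole source only if both lists rise alike with them. In males the macrophage mean was itself higher with the PGR vector, by 0.329 log2, so a part stays open. More lymphocytes, which a sort for Pcm1 should remove, were not tested and stay open, with marker reads of 2.42 to 3.36 CPM in Con_F and 3.05 to 5.65 in PGR_F, highest in PGR_F 1, where the interferon mean was also highest (1.27), but in males PGR_M 1 had the highest interferon mean (0.80) with 1.92 CPM, under Con_M 1 (2.46 CPM, interferon mean -0.36). A response of myocyte nuclei, a changed state of other nuclei, and a difference between vector preparations rather than their insert stay open and were not tested.

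Con_F 4 stood apart from the other control females in Y-linked reads, and also in other genes, though by the count below not more than Con_F 1. Its 4 Y-linked genes had the proportions of the male libraries (resampled chi-square p = 0.679), so male nuclei or reads at about 1.01% of the male level could be their source. That admixture as the cause of the distance in other genes is argued against, since Con_F 4 lay 80.1% of the way from Con_F 1 to 3 to PGR_F on the 424 genes with an unadjusted p under 0.01 between the male groups, a list that includes genes picked by chance. The same position of 80.1%, inside the range of PGR_F (77.2% to 139%), is what a PGR-vector library under a wrong label would show. That position cannot decide the label, since Con_F 4 alone was kept out of the control reference and no other Con_F library was. Con_F 4 had a control-like Pmepa1 level of 43.0 CPM. Pmepa1 also passed in the averaged comparison with Con_F 4 left out (log2 fold change -0.51, SE 0.047, edgeR adjusted p = 0.000551). Its choice thus did not rest on that library. As 1 gene picked from a ranking, it does not settle the label. The interferon list mean of Con_F 4 lay inside the range of PGR_F. The lower end of that range, PGR_F 4, was itself at the level of Con_F 2, so this does not bear on the label. A batch stays open as the labels give none. An earlier test counted genes more than 0.5 log2 under the other 3 Con_F libraries, 29 of 8005 for Con_F 4 and 70 for Con_F 1. Over them were 62 and 64, against at most 13 under and 4 over for Con_F 2 and 3. That test placed Con_F 1 further apart than Con_F 4, decided nothing, and was replaced by the position above.

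Abundant heart genes such as Cox4i1, Cpt1b and Myom1 had 0 counts. Of 652 protein-coding genes lying at least 99% inside genes of the same strand, 89.9% were at 0 in every library, against 22.4% of those inside genes of the other strand only, so reads in shared regions were likely left out of the counts. That these genes are silent in the nuclei is argued against, since 16.6% of protein-coding genes that overlap no other gene on the strand were at 0.

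Other splits of the same libraries were compared with the real groups. Where the real count of genes was 0, every split called as many by construction, so 35 of 35 in females (at most 38 in another split), 10 of 10 in males (at most 0) and 100 of 100 for the difference between the sexes (at most 351) decide nothing. For lists in females 29 of 35 splits called as many (at most 16), and in males 5 of 10 (at most 14), too few splits for a share under 0.05. For the averaged effect 100 of the 700 arrangements were used, the real one and others drawn at random. Of these, 8 of 100 splits called as many genes (at most 107) and 84 as many lists (at most 18). But only the real one, 1 of 100, reached 2390 genes at an unadjusted p under 0.05 (at most 1927 in another). As small a camera p for interferon was reached by 3 of 100, the real one included. The others went down, not up, and exchanged the vector labels of all male libraries. For females alone 4 of 35 splits had as many genes at an unadjusted p under 0.05 as the real 1765 (at most 2709) and 5 as small an interferon p, so chance was not excluded there. For the difference between the sexes the splits exchanged sex labels within each vector. A sex difference shared by both vectors enters such splits, so they do not show what chance gives for this comparison. The real 525 genes were reached there by 63 of 100 splits (at most 3043) and the interferon p by 17. In the control sex difference the real 2003 genes were reached by 3 of 35 splits (at most 2559) and the interferon p by 3. For the difference between the sexes 58 of 100 splits called as many lists (at most 18), with the same limit. For the sex difference in controls 3 of 35 splits called as many genes (at most 132) and 5 as many lists (at most 16), and in PGR-vector ventricles 1 of 10 (at most 0) and 9 of 10 (at most 20), again too few splits. The split with 38 genes set Con_F 1 to 3 against Con_F 4 and PGR_F, and so kept most of the real groups. That with 351 genes exchanged the sex labels of Con_F 1 to 3 and Con_M. Its contrast thus added the sex differences under both vectors instead of subtracting them. The splits with 107 and 132 genes mixed libraries of the groups. Whether chance or some further structure of the samples gave these counts was not tested.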

How the results depend on the processing

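The fits without Con_F 4 and Con_M 3 together and with the mean of the endothelial and fibroblast lists as a covariate were chosen only after the results were seen. Of 4326 alternative values of 207 named gene results, 4232 kept their direction and side of the threshold, 60 passed it anew, 33 no longer passed and 1 reversed: Rplp0 in the control sex difference, -0.063 with the covariate against 0.187. Those no longer passing were mainly Adcy8 (7 settings), Ano5 and Ddx3x (6 each). Of 140 alternatives outside single left-out libraries for counts, lists and agreement, 98 kept their value within 1.5 times or the spread.

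Counts of genes changed moved as follows. In females no filter gave 25, the strict filter 1, DESeq2 81 and leaving out Con_F 4 and Con_M 3 together 16, and single left-out libraries 0 to 20. In males no filter gave 12, the strict filter 1, only the compared groups 1, DESeq2 29 and left-out libraries 0 to 3. Averaged, library size scaling gave 5, robust=FALSE 21, no filter 146, DESeq2 334, both libraries out 345, the covariate 4, a fold of at least 1.5 gave 0 and left-out libraries 1 to 338. For the difference between the sexes no filter and DESeq2 gave 1 each and left-out libraries 0. In the control sex difference no filter gave 131, only the compared groups 17, DESeq2 224, the covariate 10 and left-out libraries 14 to 99. In the PGR-vector sex difference no filter gave 51, the replicate block 35, only the compared groups 56, DESeq2 80, both libraries out 44 and left-out libraries 10 to 44. With fewer libraries or other sets of genes the spread and the adjustment change by construction; otherwise the cause was not tested.

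Lists passing numbered 0 with an estimated correlation in each of the 6 comparisons, and with fry 0 in females, 1 in males, 1 averaged, 0 for the difference, 1 and 1 for the sex differences. The covariate left 2 for the difference between the sexes and 8 in controls. Left-out libraries gave 3 to 10 in females, 6 to 13 in males, 4 to 7 averaged, 3 to 12 for the difference, 11 to 15 in controls and 3 to 7 with the PGR vector, and no call turned its direction. The correlation between the sexes, 0.307, was 0.438 with the strict filter, 0.421 with both libraries out and 0.194 to 0.357 with left-out libraries.

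Replicate numbers do not pair the samples: libraries of the same number correlated between -0.245 and 0.247. Under other scalings the median log2 fold change over all genes was at most 0.067 from 0. Only the compared groups could not be fitted alone for the averaged effect and the difference between the sexes. Depth limits genes under 0.0945 CPM in the shallowest library.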

Other observations

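The tests of hypoxia and TGF-beta targets were written before their results were seen, but the ideas and the genes in the first paragraphs were chosen only after the results were seen.

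Among 109 genes with an edgeR adjusted p under 0.1 in the averaged vector effect, several are known as interferon-inducible or antigen presentation genes, picked from the ranking without a test of enrichment. The GTPases Irgm1, Irgm2 and Tgtp2 had log2 fold changes of 0.95 (SE 0.20), 1.62 (SE 0.30) and 3.59 (SE 0.71), and the class I genes H2-Q7 and H2-T22 of 1.32 and 1.13, while H2-K1 (1.31) and B2m (1.41) are members of the interferon list. Below 0 were the collagen prolyl hydroxylase genes P4ha1 (-0.53, SE 0.12) and P4ha2 (-0.34, SE 0.07), the mitochondrial gene Higd1a (-0.33, SE 0.07), and the troponins Tnnt1 (-0.71, SE 0.12) and Tnnc1 (-0.48, SE 0.10), and none of the genes of this paragraph so far passed 0.05. Without Con_F 4, 338 genes passed in all. These held 13 interferon genes (among them B2m, H2-D1, Gbp2, Ifih1, Irf1, Ifit1, H2-K1, Tap1, Irf7, Gbp3, Gbp7 and Ddx58) and 4 lower glycolysis genes (Gpi1, Pfkl, Pgk1 and Pgam1). Fabp3 was higher and Tnnt1 lower, and of the p53 list Aen was lower and Trp53inp1 higher. Con_F 4 was singled out here only after the results were seen. Among the Con_F libraries it had the highest interferon mean. It also had the lowest Pgk1 (16.5 CPM, others 21.8 to 22.1) and Pgam1 (13.8 CPM, others 16.9 to 17.2). Leaving it out therefore favours the interferon and glycolysis calls.

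A set of 16 genes had a fitted male log2 fold change under -2 without a comparable drop in females. Among them were Lars2 (-3.73), Il31ra (-4.44), Camk1d (-2.87), Mir6236 (-6.37) and the ribosomal RNA genes n-R5-8s1 (-6.71) and Gm24601 (-5.45). They passed in no case (smallest edgeR adjusted p = 0.611). This choice favours genes high in Con_M, so a high share in some Con_M library follows in part from it. These 16 genes held 1.33% of the counts of Con_M 3 and 0.0426% to 0.111% in the other 12 libraries. Lars2 had 2480 CPM in Con_M 3 and 56.3 to 151 elsewhere, Il31ra 2110 and 2.88 to 165, and Mir6236 2550 and 3.32 to 80.3.

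Genes lower with the PGR vector prompted 2 hypotheses. For hypoxia-inducible genes, leaving out the 7 that prompted the idea, 14 of 19 members were below 0 in the averaged effect (median -0.04, mean -0.06, exact permutation p = 0.177). For TGF-beta and SMAD targets, leaving out 2, 11 of 16 were below 0 (median -0.06, exact permutation p = 0.407). The bound written in advance, an exact p of 0.05 or over, was too strict, since a p that misses the threshold does not show that values did not differ, so both hypotheses stay undecided.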
